A study of Mus musculus with 16 samples.

How the data were processed

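Purified spermatocytes from a reporter mouse line were sorted by flow cytometry, bound to beads and treated with antibody and protein A-Tn5 transposase, and the tagged DNA was amplified by PCR and sequenced from both ends, per the labels' protocols. The 16 samples formed 8 groups of 2 by antibody and genotype. Nothing in the labels says that the 2 libraries of a group came from separate animals. A peak list was used for 3 groups (SETX, MYBL1 and S9.6 in wild-type cells, 6 libraries), and the 10 libraries of the other 5 groups were not analysed here.

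Reads were aligned to mm10 with Bowtie2, per the submitters' processing notes. The peak caller, its settings, its control and the way in which the 2 libraries of an antibody were merged are not given in the sources used here. Each deposited list holds chromosome, start, end, name and a score per peak. All starts of the 3 lists are multiples of 100 and all ends fall on the last base before such a multiple, so positions are known to a grid of 100 bp. The score values deposited by the authors carry no stated meaning. They stop at a ceiling of 314, which 98.3% of SETX, 91.1% of MYBL1 and 100% of S9.6 peaks reach, and the lowest is 3.31. The score therefore could not rank peaks, and width (end minus start) was used wherever the design had called for the score. Each list is named for both libraries of its antibody, but its peak names carry the number of a single library. The names are numbered up to 2620 for SETX, 2160 for MYBL1 and 1777 for S9.6, while the lists hold 1424, 720 and 163 peaks. How peaks were removed or joined is not given. With a single list per antibody, peaks carry no error between libraries. Deeper libraries give more and wider peaks, so peak numbers are not compared between antibodies by a test.

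Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose chromosomes are those of mm10. The table gave gene start, end and type, without strand, exons or sequence. A gene was therefore counted as bound when a peak lay within 1 kb of either of its ends, in place of the transcription start site that the design had named, and whether a peak was exonic or intronic was not determined. Of the table, 345 rows that belong to unplaced or patch scaffolds under a chromosome's name were left out, which left 49209 genes on chromosomes 1 to 19 and X, of which 21521 were protein-coding. Names of the gene lists were matched by symbol, or else by a synonym of a single gene. Sequence composition, the MYB motif, GC skew, divergent promoters and repeat content were not determined, since no genome sequence was used here. Coordinates are counted from 1.

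Overlap meant at least 1 bp. It was tested by 10000 random placements of each peak on its own chromosome, between the first and last annotated gene or peak, with assembly gaps inside that span left in. Shares on X were tested by two-sided exact binomial tests against the X share of length (6.53%) and by Fisher's exact tests between lists. Peaks at gene ends were tested by placement and between lists by Fisher's exact test. Genes bound by 2 antibodies, and members of 12 gene lists, were tested by two-sided Fisher's exact tests among protein-coding genes. Mean log2 width was compared by 100000 permutations of the labels. Adjusted p-values are Benjamini-Hochberg values within each family, whose size is given with the result, and the threshold was 0.05. Intervals of shares are Wilson intervals and those of odds ratios are log-normal, or exact where a cell was 0. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots by matplotlib 3.10.9.

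The tests were also run on simulated data, with calls at an unadjusted p under 0.05. The list size and the planted odds ratio and width difference lie near the values observed in the results. With SETX and MYBL1 peaks of the real widths placed at random, 0.5% of 200 simulations gave p under 0.05, and with 10 planted overlaps all 200 did so, with 10.02 recovered on average. Lists whose peaks favour the same places were not simulated. For a list of 32 genes among 21521, the Fisher test called 4.6% of 1000 simulations with no enrichment and 88.3% with an odds ratio of 8. Gene lists in the results were called by adjusted p over 36 tests, which is stricter, so 88.3% overstates the power there. For SETX width, 5.5% of 1000 simulations with no difference were called, and a planted difference of 0.8 on the log2 scale was recovered as 0.80.

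The gene lists, a rule for named genes, and the tests of overlap, X share, gene ends, shared genes, gene lists and shared width were fixed before the data were examined. Ranking by width in place of the score, gene ends in place of start sites, and the tests of X against autosomes for overlap, bound genes and width, of clusters, of local families and of chromosome starts, and the counts along X, were settled after the data were seen. In the form used, the rule named the 10 protein-coding genes with the widest peak of each antibody, the 10 genes highest by summed width rank for each pair and for all 3, up to 8 bound members of each list, and the 3 widest peaks of each antibody. Alternatives changed the overlap that counts as shared (50% of the shorter peak, or peaks within 1 kb), the placement (at gene ends, or a circular shift), the window (500 bp, 2 and 5 kb), the genes used, the expected X share, and the peaks kept (without those wider than 5 kb, or merged within 1 kb). Chosen after the data were seen were the widest 50% of peaks, peaks at the ceiling score, X and autosomes apart, gene bodies, peaks merged within 20 kb, and peaks away from local gene families. A local family was a set of genes whose symbols share a letter stem with at least 2 others within 500 kb.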

Results

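Binding profiles were made from purified spermatocytes of mouse testis by CUT&Tag, in which an antibody bound to chromatin directs a protein A-Tn5 transposase to cut and tag the DNA beside it. The study design names senataxin (SETX), an RNA-DNA helicase, and R-loops, in which RNA pairs with 1 strand of DNA and displaces the other, in pachytene spermatocytes. The 16 libraries fell into 8 groups of 2. Wild-type cells were profiled with antibodies to SETX, to the pachytene transcription factor MYBL1, with the hybrid-binding antibody S9.6, and with IgG, H3K4 trimethylation and phosphorylated H2AX antibodies. Setx knockout cells were profiled with IgG and phosphorylated H2AX antibodies. Peak lists for SETX, MYBL1 and S9.6 were analysed, each a single list for the 2 libraries of its antibody, and the 10 libraries of the other 5 groups were not analysed here. With 1 list per antibody there was no value per library, so no spread between replicates could be measured, and the read depth of the libraries is unknown. Intervals below are Wilson or odds ratio intervals at the 95% level and cover the counting of peaks or genes only.

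SETX gave the most and widest peaks. It had 1424 peaks covering 1207 kb, with a median width of 599 bp (quartiles 299 and 1099 bp). MYBL1 had 720 peaks covering 393 kb, with a median width of 499 bp. The S9.6 antibody had 163 peaks covering 68.5 kb, with a median width of 299 bp. No list held a peak on the Y chromosome. The widest SETX peak, of 7899 bp, covered Gm9 (X, 37204301 to 37212199, mm10). The next lay over Tbc1d25 (X, 8171301 to 8178199) and over Gm4779 and 8030474K03Rik (X, 101790301 to 101796699). The widest MYBL1 peak, of 6299 bp, lay outside annotated genes, 1679 bp from the cell cycle inhibitor gene Cdkn1a (17, 29102401 to 29108699), and the next lay in Btbd11 (10, 85413201 to 85419399). The third widest MYBL1 peak covered the ribosomal RNA pseudogene Rn18s-rs5 (17, 39843901 to 39848899), with a deposited score of 11.03 against the ceiling of 314. The 3 widest S9.6 peaks lay together on chromosome 16 (3245401 to 3247499, 3234901 to 3236499 and 3238901 to 3240499), outside annotated genes.

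SETX occupancy was concentrated on the X chromosome, which pachytene cells of males silence and wrap in the sex body. Of the 1424 SETX peaks, 1016 lay on X, or 71.3% (68.9 to 73.6), where the X share of the annotated genome length gives 6.53%. SETX had 6.06 peaks per Mb on X and 0.170 per Mb on autosomes, a ratio of 35.7. MYBL1 had 123 of 720 peaks on X, or 17.1% (14.5 to 20.01), at 0.733 peaks per Mb against 0.249 on autosomes. S9.6 had 39 of 163 peaks on X, or 23.9% (18.03 to 31.0). Of these X peaks, 121 of the 123 for MYBL1 and 27 of the 39 for S9.6 coincided with SETX peaks. Each share exceeded the share of length by a two-sided exact binomial test. The Benjamini-Hochberg adjusted p over 6 tests of X shares was 4.3e-22 for MYBL1 and 1.4e-12 for S9.6, and for SETX the upper tail had a log10 p of -847. The odds of lying on X were 12.1 times higher for SETX than for MYBL1 peaks (9.65 to 15.1, Fisher's exact test, adjusted p = 1.8e-131) and 7.92 times higher than for S9.6 peaks (5.43 to 11.6, adjusted p = 1.2e-31). For MYBL1 against S9.6 the odds ratio was 0.655 (0.435 to 0.986, Fisher's exact test, adjusted p = 0.044), a call that ended when the widest 50% of each list was used (0.880, adjusted p = 0.743), at the ceiling score (0.676) and without peaks wider than 5 kb (0.657). Neighbouring peaks are not independent, so these p-values are too small. No IgG list was used here, so background common to all antibodies was not subtracted.

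**Figure D1:**
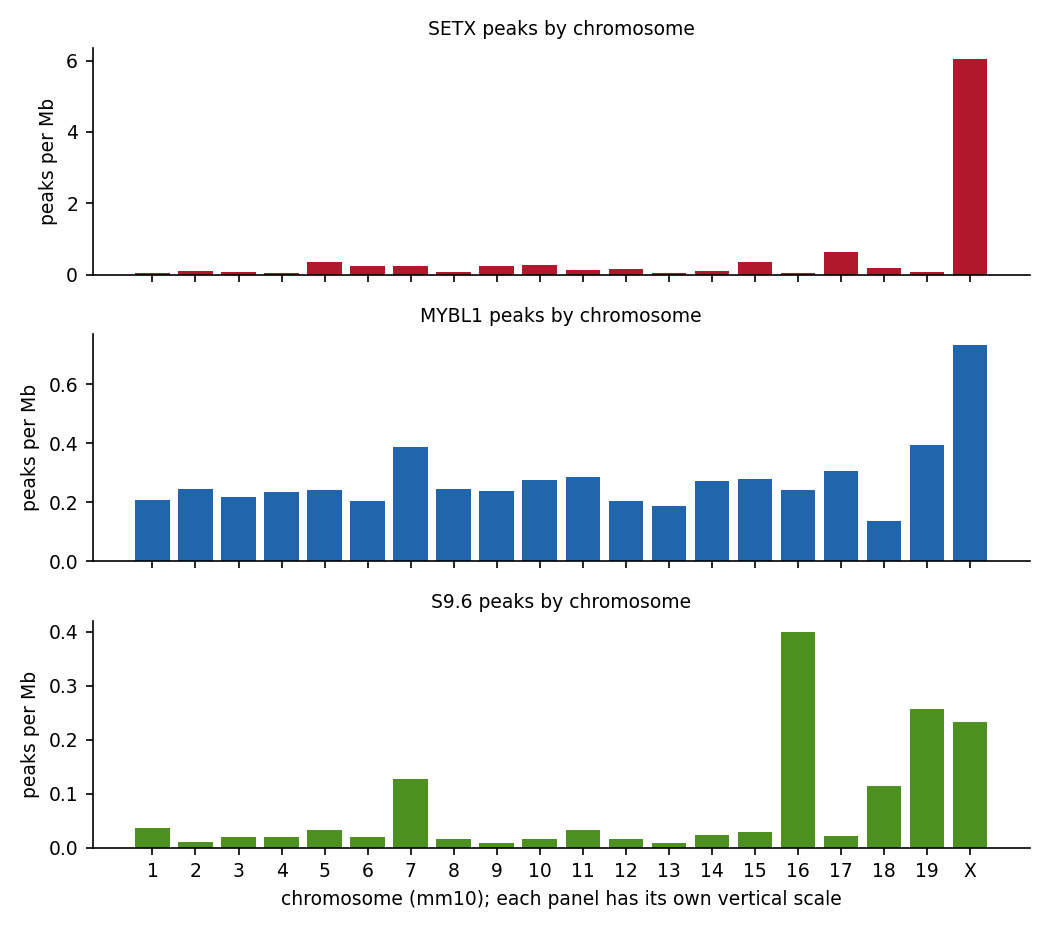
Bars give the peaks per Mb of annotated length on each chromosome (mm10) for SETX, MYBL1 and S9.6, with a separate vertical scale in each panel. SETX reached 6.06 peaks per Mb on X and at most 0.621 on an autosome (chromosome 17), whereas S9.6 was densest on chromosome 16, at 0.400 peaks per Mb.

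SETX peaks were spread along X. All 18 windows held SETX peaks, with a median of 53.5 and a range of 7 to 144 per window. Windows were of 10 Mb except the last, from 170 to 170.9 Mb, which held 24 SETX peaks, the most for its length. The window from 30 to 40 Mb held the most peaks for SETX (144), MYBL1 (20) and S9.6 (13). Among protein-coding genes, Dmd, the long dystrophin gene, held 25 SETX peaks over 2390 kb, and Scml2, a Polycomb protein of the sex body, held 19 peaks over 176 kb. Fsip2l and Mid1 held 8 peaks each, and Xk held 7. These 5 genes were chosen after their values were seen. SETX peaks on X were also wider than those on autosomes, with medians of 699 and 399 bp. The difference of mean width was 0.62 on the log2 scale (two-sided permutation test, adjusted p = 3.0e-05 over 3 lists, the smallest the permutations can give). MYBL1 peaks had a median of 499 bp in both places (difference 0.06 on the log2 scale, permutation test, adjusted p = 0.579), and S9.6 peaks had medians of 199 bp on X and 399 bp on autosomes (difference -0.29, adjusted p = 0.201).

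**Figure D2:**
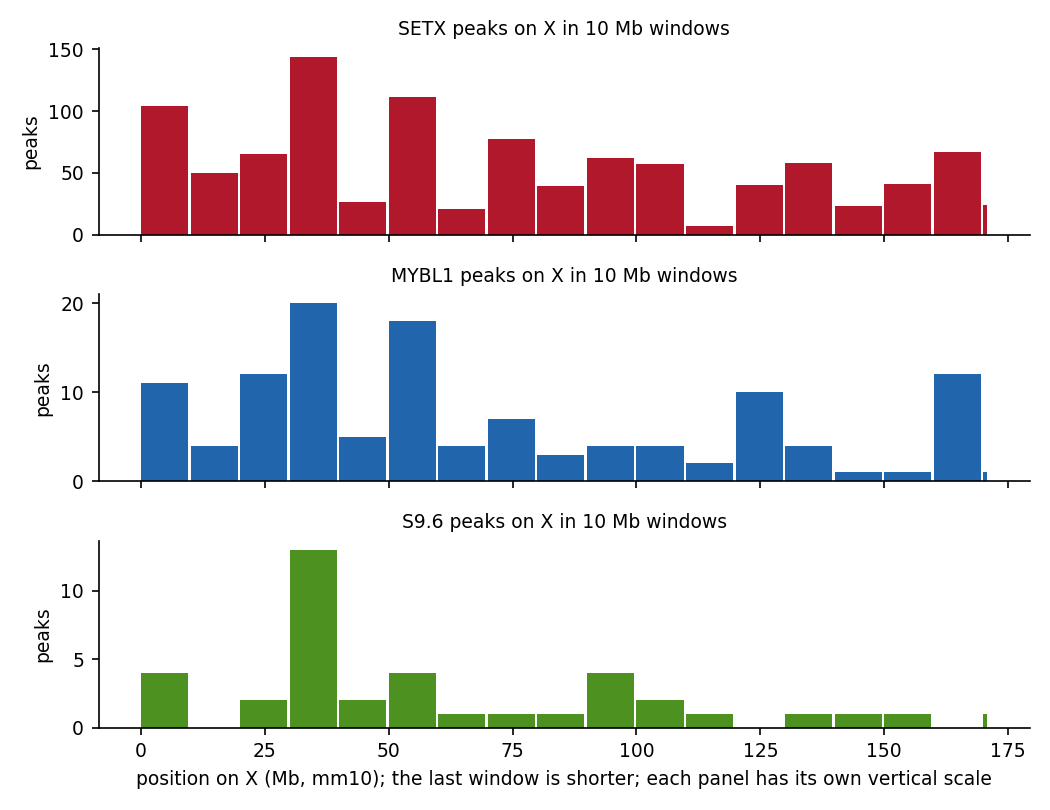
Bars count SETX, MYBL1 and S9.6 peaks in 10 Mb windows along X (Mb, mm10), with a separate vertical scale per panel and a shorter last window. SETX peaks were present in all 18 windows and numbered 144 between 30 and 40 Mb.

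On X, almost every MYBL1 peak and most S9.6 peaks coincided with a SETX peak. Of the 123 MYBL1 peaks on X, 121 overlapped SETX by at least 1 bp, or 98.4% (94.3 to 99.6), against 83 of 597 autosomal MYBL1 peaks, or 13.9% (11.4 to 16.9). Of the 39 S9.6 peaks on X, 27 overlapped SETX, or 69.2% (53.6 to 81.4), against 8 of 124 on autosomes, or 6.45% (3.31 to 12.2). These differences between X and autosomes passed Fisher's exact test (odds ratio 375, adjusted p = 9.1e-78 for MYBL1, and 32.6, adjusted p = 2.6e-14 for S9.6, over 6 ordered pairs). They include the higher density of SETX on X, since random placement gave 1.09 overlapping MYBL1 peaks on X and 0.123 on autosomes, and 0.313 and 0.0156 overlapping S9.6 peaks. Relative to placement the overlap on X was 111 times for MYBL1 and 86.4 times for S9.6, against 675 and 513 times on autosomes. These ratios cannot be compared, and the contrast was not tested itself. Even with all 123 MYBL1 and all 39 S9.6 peaks on X overlapping SETX, the ratios there could not reach the autosomal values. Of SETX peaks, by contrast, 117 of 1016 on X overlapped MYBL1, or 11.5%, against 83 of 408 on autosomes, or 20.3%. This pair also passed, in the opposite direction (odds ratio 0.510, 0.374 to 0.694, Fisher's exact test, adjusted p = 6.3e-05). That direction follows from list sizes, since X held 123 MYBL1 peaks for 1016 SETX peaks, and autosomes held 597 for 408. With 121 of the 123 already overlapping, the SETX share on X had little room to rise, so it does not show weaker sharing there. MYBL1 and S9.6 peaks overlapped each other on X and autosomes without a difference past the threshold (12.8% against 7.26% of S9.6 peaks, odds ratio 1.88, Fisher's exact test, adjusted p = 0.391). Peak lists alone cannot separate shared binding on X from background common to the antibodies or from cross-talk between libraries, so these shares are of coinciding peaks only.

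**Figure D3:**
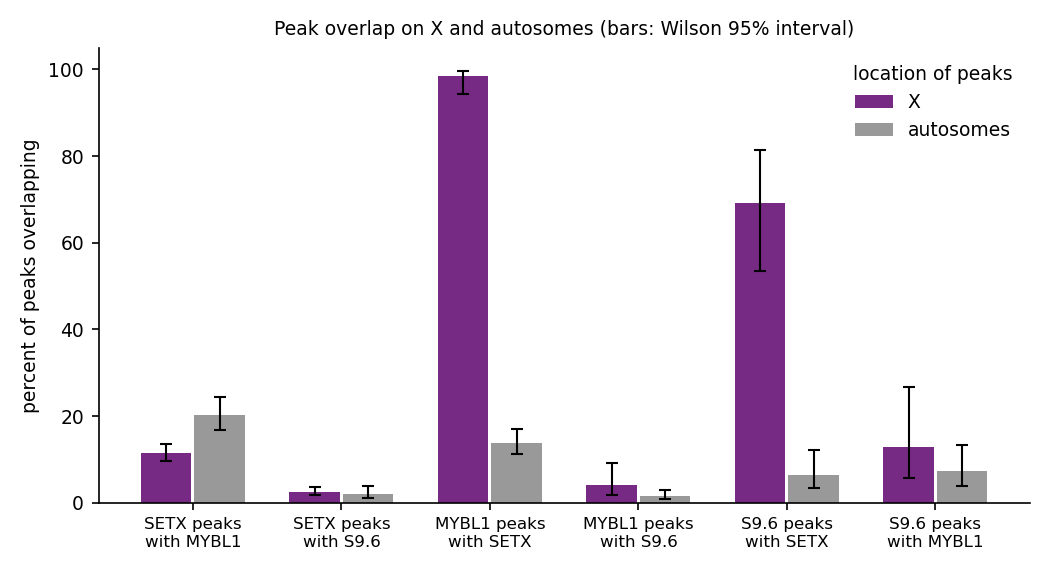
Bars give the percent of peaks of each list that overlap a peak of a second list by at least 1 bp, split into peaks on X and on autosomes, with Wilson 95% intervals as error bars. MYBL1 peaks overlapped SETX at 98.4% on X and 13.9% on autosomes, and S9.6 peaks at 69.2% and 6.45%.

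Over all chromosomes, each pair of lists shared far more sites than random placement gave. SETX and MYBL1 shared 200 SETX peaks, where 10000 random placements on the same chromosomes gave 1.19 on average and at most 7. SETX and S9.6 shared 34 SETX peaks (mean 0.328, at most 4), and MYBL1 and S9.6 shared 14 MYBL1 peaks (mean 0.0583, at most 2). All 3 lists met at 9 SETX peaks, against 0.0416 by placement. The excess was smaller when only peaks at gene ends were taken and placed at random among gene ends. SETX then shared 102 peaks with MYBL1 against 4.83, and 15 with S9.6 against 0.627, MYBL1 shared 10 with S9.6 against 0.0829, and all 3 lists met at 9 against 0.341. Ends were drawn from all protein-coding genes of the chromosome, so a preference of the antibodies for the same kind of gene end was not removed. The H3K4 trimethylation and IgG libraries, which were not analysed here, would be needed for that. Each of the 7 two-sided placement tests, at gene ends as well, had an adjusted p of 0.0002, the smallest that the placements can give. The 9 shared sites lay at the nonsense-mediated decay gene Smg7, the RNA-binding protein gene Pcbp3, the splicing factor gene Tra2b, the homeobox gene Pknox1 and the kinase gene Wnk3, and at Gm14594, Gm14595, Gm14590 and Gm6664, which lie between 54439601 and 55797799 on X. Of these genes, Gm6664 lay outside the naming rule and was named after its value was seen. The Wnk3 site (X, 151167901 to 151170999) had a SETX peak of 3099 bp, a MYBL1 peak of 1199 bp and an S9.6 peak of 499 bp.

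SETX and MYBL1 favoured gene ends, and S9.6 did so less. Within 1 kb of either annotated end of a protein-coding gene lay 485 SETX peaks, or 34.1% (31.6 to 36.6), against 3.38% by random placement. MYBL1 had 273 such peaks, or 37.9% (34.4 to 41.5), against 3.81%, and S9.6 had 23, or 14.1% (9.59 to 20.3), against 3.54%. Each list exceeded random placement in a permutation test of peak positions (adjusted p = 0.00024 over 6 tests, from the smallest p the placements can give). By Fisher's exact test, the odds of lying at a gene end were higher than for S9.6 both for SETX (odds ratio 3.14, 2.00 to 4.95, adjusted p = 2.1e-07) and for MYBL1 (3.72, 2.33 to 5.92, adjusted p = 8.0e-09). SETX and MYBL1 did not differ past the threshold (odds ratio 0.846, 0.702 to 1.02, exact test, adjusted p = 0.0851), although a window of 500 bp placed the ratio at 0.779 (adjusted p = 0.0114), and it crossed 1 on autosomes (1.002), within 5 kb (1.04) and for the widest 50% (1.27). Outside every annotated gene and away from protein-coding gene ends lay 36.2% of SETX, 35.6% of MYBL1 and 57.1% of S9.6 peaks. Start and stop of a gene could not be told apart, since the annotation used gave no strand.

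X-linked genes carried SETX far more often than autosomal genes. SETX had a peak at an end of 292 of 963 X-linked protein-coding genes, or 30.3% (27.5 to 33.3), and of 193 of 20558 autosomal genes, or 0.939% (odds ratio 45.9, 37.7 to 55.9). MYBL1 peaks lay at 41 X-linked genes, or 4.26%, and 263 autosomal genes, or 1.28% (odds ratio 3.43, 2.45 to 4.80), and all 41 of the former also carried SETX. S9.6 peaks lay at 6 X-linked and 18 autosomal genes, 0.623% and 0.0876% (odds ratio 7.15, 2.83 to 18.1). The adjusted p-values by Fisher's exact test over 3 lists were 2.3e-277, 4.4e-10 and 0.00053. The 10 genes with the widest SETX peaks were all X-linked. Besides those at the widest peaks, they were the testis gene Tsga8 (5699 bp), Ppp1r3f (5299 bp), the neighbours Bcap31 and Abcd1, a peroxisomal fatty acid transporter, under a single 5299 bp peak (X, 73714101 to 73719399), 1700080O16Rik (4999 bp) and the cyclin-dependent kinase gene Cdk16 (4399 bp).

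The genes with the widest MYBL1 peaks were mostly autosomal. They included Smpd5 (1799 bp; 15, 76293801 to 76295599), Lpar2 and the homeobox gene Pbx4 under a single 1399 bp peak (8, 69831401 to 69832799), Zmym6 (1199 bp), the corepressor gene Trim28 and its neighbour Gm31649 (1099 bp) and the translation factor gene Eif5a (1099 bp). X-linked Usp26, a deubiquitinase gene (1499 bp; X, 51800101 to 51801599), Wnk3 and Mid1 (1199 bp each) completed the 10. A SETX peak also lay at 8 of these 10 genes, the exceptions being Zmym6 and Eif5a. The 8 are not separate sites, since Lpar2 with Pbx4 and Trim28 with Gm31649 each had a single SETX peak between them. They also include X-linked Usp26, Wnk3 and Mid1. Of all 304 genes with MYBL1, 117 had SETX, and of the 263 autosomal ones, 76 did. The genes with the widest S9.6 peaks were Slc22a28 (599 bp; 19, 8132701 to 8133299), then Smg7, the chromatin remodeller gene Srcap, Tra2b and Wnk3 (499 bp each), Fcgr3, Tsc22d1 and the cullin gene Cul2 (399 bp each), and Tada1 and Pcbp3 (299 bp each). Of these 10 genes, 5 also had a SETX peak (Smg7, Srcap, Tra2b, Wnk3 and Pcbp3), against 14 of all 24 genes with S9.6.

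Genes with a peak of one antibody tended to carry the others. By Fisher's exact test over 3 pairs, SETX and MYBL1 shared 117 genes, against 6.85 for independent lists (odds ratio 35.4, 27.5 to 45.7, adjusted p = 3.3e-114). By the same exact test SETX and S9.6 shared 14 genes, against 0.541 (odds ratio 62.5, 27.6 to 141, adjusted p = 1.7e-17), and MYBL1 and S9.6 shared 10, against 0.339 (odds ratio 51.5, 22.7 to 117, adjusted p = 4.5e-13). On X, all 6 genes with S9.6 also had SETX, as did all genes with MYBL1. Among autosomal genes the odds ratio for SETX and MYBL1 was 70.1 (50.8 to 96.8). These tests take all protein-coding genes as background, so a preference of the antibodies for the same kind of gene, or common background, was not removed. The pair of SETX and MYBL1 ranked highest by width at Usp26, Wnk3, Ppp1r3f, Gm16430, Slxl1, a member of the multicopy Slx family, Tbc1d25, Fam122b, the fragile X gene Fmr1, Gm16405 and Gm31649. At Fmr1 a SETX peak of 3599 bp (X, 68676501 to 68680099) spanned a MYBL1 peak of 699 bp (X, 68678201 to 68678899). Genes shared by SETX and S9.6 included Yipf6, Gm2854, Srcap and the neighbours Dnajb4 and Fubp1, and those shared by MYBL1 and S9.6 included Tada1 and the signalling gene Smad2. Peaks at Gm16430, Gm16405, Slxl1, Gm14590, Gm14594 and Gm14595 are uncertain as to the gene, since reads of similar neighbouring copies are hard to assign.

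Of 12 gene lists, genes of the DNA damage response and sex chromosome silencing passed the test for SETX. SETX lay at 5 of their 32 members, or 15.6%, against 2.23% of other genes (odds ratio 8.11, 3.11 to 21.1, Fisher's exact test, adjusted p = 0.025 over 36 tests). The 5 were Ube2a and Scml2 on X (SETX peaks of 1099 bp each), and on autosomes Setx itself (199 bp; 2, 29124301 to 29124499), Atf7ip, a partner of the methyltransferase SETDB1 (199 bp), and H2ax (99 bp; 9, 44335301 to 44335399), whose phosphorylated product marks the sex body. In the same exact test the call was lost when the gene body was added (odds ratio 6.87, adjusted p = 0.051), with windows of 500 bp (5.04, adjusted p = 0.316) and 5 kb (6.47, adjusted p = 0.0658), and for the widest 50% (4.82, adjusted p = 0.639), and it was kept among autosomal genes (11.9, adjusted p = 0.0494). MYBL1 lay at 3 members of this list, Rnf168, Atf7ip and Setx (exact test, adjusted p = 0.123).

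The list of replication-dependent histones had SETX at 6 of 67 members, or 8.96%, which missed the threshold (odds ratio 4.31, 1.85 to 10.01, exact test, adjusted p = 0.0715). Its members were taken by a pattern of gene symbols, and whether each is replication-dependent was not checked. The 6 genes were 3 pairs of neighbours, H3c15 with H2ac19 and H2ac18 with H3c14 on chromosome 3 and H2bc1 with H2ac1 on chromosome 13. Each pair lay at a single SETX peak, so the 6 genes rest on 3 peaks and are not independent as the test assumes. With autosomal genes alone as background, where SETX is rare, the odds ratio was 10.7 (4.56 to 25.01, exact test, adjusted p = 0.0014), a setting chosen after the data were seen, with a p too small for the same reason. MYBL1 lay at 4 of the 67, H2ac18, H3c14, H2bc1 and H2ac1 (exact test, adjusted p = 0.134).

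No other list passed Fisher's exact test for any antibody among all protein-coding genes. Of the meiotic prophase genes, 2 of 45 had MYBL1, Sycp1, which encodes a part of the synaptonemal complex, and the crossover gene Msh5 (exact test, adjusted p = 0.478), and none had SETX. Of the meiotic division genes, 2 of 26 had MYBL1, the chaperone gene Hspa2 and Nek2 (exact test, adjusted p = 0.266), and the cyclin gene Ccnb3 had SETX. Of the R-loop factors, 3 of 27 had SETX, namely Thoc2 (2599 bp), the helicase gene Ddx5 and Setx (odds ratio 5.45, exact test, adjusted p = 0.160), and Setx had MYBL1 as well (adjusted p = 0.830). Of the spermatid genes, 2 of 44 had SETX (Odf2 and Akap4) and 1 had MYBL1 (Ldhc), with adjusted exact p of 0.830 and 0.931. Of the regulators of meiosis, Taf7l alone, of 24 members, had SETX (4299 bp) and MYBL1 (299 bp), with adjusted exact p of 0.931 and 0.830. Ribosomal protein genes had SETX at 4 of 82 (Rpl10, Rpl36al, Rpl36a and Rplp0, exact test, adjusted p = 0.478) and MYBL1 at 2 (Rplp0 and Rps9, adjusted p = 0.830). Zinc finger genes had SETX at 4 of 397 (Zfp711, Zfp664, Zfp768 and Zfp654, odds ratio 0.437, exact test, adjusted p = 0.478) and MYBL1 at 1 (Zfp711, odds ratio 0.174, adjusted p = 0.266). None of the 25 piRNA pathway genes and none of the 25 markers of Sertoli, Leydig, peritubular cells and macrophages had a peak of any antibody at an end. Of the 22 spermatogonial genes, X-linked Rhox13 had SETX (exact test, adjusted p = 0.931). S9.6 lay at no member of any list. With 24 genes carrying S9.6, an absence from lists this small is not informative.

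SETX peaks shared with MYBL1 were wider than the rest. Their median width was 1199 bp in 200 shared and 499 bp in 1224 unshared peaks, a difference of mean width of 0.82 on the log2 scale (two-sided permutation test, adjusted p = 6.0e-05 over 6 ordered pairs, from the smallest p the permutations can give). In permutation tests on X the difference was 1.54 on the log2 scale (adjusted p = 6.0e-05), and on autosomes it was -0.05 (adjusted p = 0.842), although the contrast between X and autosomes was not tested itself. None of the other 5 ordered pairs passed. MYBL1 peaks shared with SETX had a median of 499 bp, as did the unshared (difference -0.03, permutation test, adjusted p = 0.759). A wide peak also overlaps more by chance, which the permutation does not remove.

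On autosomes, SETX peaks gathered in a small number of loci. There were 19 clusters of at least 4 peaks with gaps of at most 20 kb, and they held 185 of the 408 autosomal SETX peaks. The largest, on chromosome 17 (27295701 to 27358599), held 29 peaks over 62.9 kb around the non-coding gene Gm10505 and the microRNA genes Mir7214, Mir7216, Mir7217 and Mir7218. Others lay on chromosome 5 (113322201 to 113357899, 20 peaks, with Mir7229 and Mir7230), 6 (127782101 to 127815299, 15 peaks, with Mir7233), 9 (67710401 to 67760499, 14 peaks, with Mir7241, Mir7242 and C2cd4b), 7 (73786801 to 73836599, 13 peaks, with Mir7234) and 18 (67049301 to 67088899, 13 peaks, reaching an end of Gnal). Clustered peaks lay at gene ends in 5.41% of cases, against 65.5% of the 223 other autosomal SETX peaks (Fisher's exact test, p = 5.7e-40). They overlapped a MYBL1 or S9.6 peak in 4.32% of cases (2.21 to 8.30), against 35.4% (29.4 to 41.9) of the others (exact p = 5.9e-16). Both tests count peaks as independent, but the 185 clustered peaks lie in 19 loci, so the p-values are too small and the intervals too narrow. MYBL1 had 6 autosomal clusters by the same definition and S9.6 had 4. The clusters and their tests were chosen after the data were seen.

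**Figure D4:**
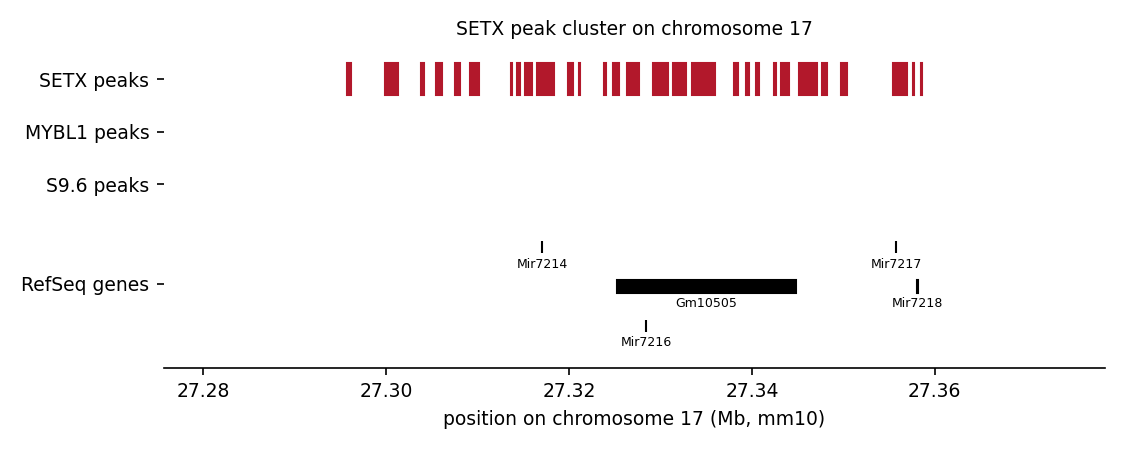
Boxes mark SETX, MYBL1 and S9.6 peaks and annotated genes along chromosome 17 (Mb, mm10), with 20 kb on either side of the largest autosomal SETX cluster. The 29 SETX peaks spread over 62.9 kb, and no MYBL1 or S9.6 peak lay in the plotted window.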

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

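The comparison of SETX with MYBL1 was planned, but its use as a test of an excess common to all antibodies, and the removal of genes with Gm names, were chosen only after the result was seen. Marked by a difference between antibodies in the odds of lying on X, by Fisher's exact test, were SETX against MYBL1 (odds ratio 12.1), SETX against S9.6 (7.92) and MYBL1 against S9.6 (0.655).

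The concentration of SETX peaks on X was weighed against technical sources. Reads shared among local gene families would remove the excess once peaks within 50 kb of such families were left out, but 69.6% (67.0 to 72.1) of the 1255 peaks left lay on X, and 66.2% when Gm-named coding genes, which the family definition misses, were left out too. A small number of dense clusters would also remove it, but after merging peaks over gaps of 20 kb, 68.7% (65.1 to 72.0) of 689 regions lay on X. An X excess of the same size for every antibody is at odds with the ratio of 12.1 (9.65 to 15.1) against MYBL1, although a smaller excess common to all 3 antibodies stays open, since the IgG libraries were not analysed here. No biological explanation was tested.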

How the results depend on the processing

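Alternatives chosen after the data were seen were the widest 50%, the ceiling score, X or autosomes alone, gene bodies, merging within 20 kb and the removal of local families. No paired analysis was possible because each antibody has a single merged list with no value per library, and for the same reason leaving out a replicate was not possible. Of 236 alternative values of results with a test, 218 neither reversed nor crossed the threshold. All 63 overlap values among them had the smallest p the placements can give, as had the 7 reported, so their p cannot show a weaker excess. Results without a test were held to a tolerance: all 9 alternative peak numbers and 21 of 27 counts of gene lists were within 1.5 times the count reported, and 8 of 9 median widths were within the bootstrap 95% interval of the median. The counts of gene lists for MYBL1 and S9.6 were 0 in every setting, which such a tolerance cannot judge. The 6 counts that moved were all for SETX, so its call was not stable. The X odds ratio of MYBL1 against S9.6 lost its call at the ceiling score (0.676), for the widest 50% (0.880) and without peaks wider than 5 kb (0.657). The gene-end odds ratio of SETX against MYBL1 passed within 500 bp (0.779) and crossed 1 within 5 kb (1.04), for the widest 50% (1.27) and on autosomes (1.002), without a call. The SETX median width was 699 bp after merging within 1 kb, which joins peaks by construction, and took the number of SETX peaks to 1102 and the S9.6 median, within its interval, to 399 bp. The 1 gene list called for SETX became 0 within 500 bp, within 5 kb, with gene bodies, for the widest 50% and on X, where a single list had enough members, and 2 on autosomes. Mean log2 width of SETX peaks shared with MYBL1 reversed on autosomes (-0.053, permutation test, adjusted p = 0.842). Reversals without a call on either side were MYBL1 widths shared with SETX at the ceiling score (0.019) and on X (0.58), MYBL1 with S9.6 on autosomes (-0.16), and on X S9.6 with SETX (0.38) and with MYBL1 (0.10). The cause was not tested in the other cases. On X no odds ratio could be given for SETX with MYBL1 or S9.6, since all of their genes had SETX. Not run, for want of strand or sequence, were repeat masking, CpG-rich backgrounds and all alternatives of motif, composition, skew and divergent promoters. The depth of the libraries is unknown, so absent peaks, above all for S9.6, do not show absent binding.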

Other observations

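All tests below except that of S9.6 peaks near local gene families as a whole were chosen only after the result was seen. X-linked genes in local families, sets of genes with a common symbol stem, carried SETX less often than other X-linked genes. Of 139 X-linked protein-coding genes in local families, 16 had SETX at an end, or 11.5%, against 276 of 824 others, or 33.5% (odds ratio 0.258, 0.150 to 0.443, Fisher's exact test, p = 2.8e-08). None of 27 Btbd, 9 Ssxb and 7 Samt genes had it, whereas 5 of 33 Rhox homeobox genes and all 3 Tmsb genes did. Reads of similar neighbouring copies are hard to assign, so missing peaks there do not show missing SETX. The family definition misses Gm-named genes, so Gm16405 and Gm16430, which had SETX, count among the others.

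S9.6 peaks near families were frequent on X as well as on autosomes. On X, 30.8% of S9.6 peaks lay within 50 kb of a local family, against 5.50% by placement, and for SETX on X the share was 14.0% against 5.52% (position permutation, adjusted p = 0.00036 for each over 9 tests, from the smallest p possible). MYBL1 on X had 11.4%, against 5.52% by placement (position permutation, adjusted p = 0.0231), so all 3 lists lay closer to families on X than placement gave. Placement was uniform along X, whereas the peaks favoured gene ends, so nearness to any set of genes can exceed it. On autosomes S9.6 had 39.5%, against 9.10% by placement (position permutation, adjusted p = 0.00036). MYBL1 had 10.9% there, against 8.59% (adjusted p = 0.0637), and SETX had 6.62%, against 9.02% (position permutation, adjusted p = 0.0916), so neither passed.

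The clustering of autosomal SETX peaks was weighed next. Chance spacing gave at most 1 cluster in 10000 placements, against 19 observed. Regions that any antibody calls would overlap MYBL1 or S9.6 for most peaks, and 4.32% did. That share counts peaks and not clusters, and no IgG list was used here, so it does not exclude such regions. The clusters held a microRNA gene in 7 cases (0.168 by placement, permutation p = 0.0002, the smallest possible). They had a MYBL1 peak within 5 kb in 7 cases (0.144 by placement, permutation p = 0.0002). The other 12 clusters, among them the 4 with the most peaks, had no MYBL1 peak within 5 kb. What else the loci have in common stays open, since no annotation of piRNA loci or repeats was used here.

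S9.6 peaks gathered at chromosome starts. Of 124 autosomal S9.6 peaks, 52 lay in the first 1 Mb of the annotated chromosome, or 41.9% (33.6 to 50.7), 37 of them on chromosome 16, against 1.01% of MYBL1 and 0.490% of SETX peaks. Annotated length ran from the first gene or peak of any list, S9.6 included, so a window may begin at a peak that it counts. A start excess of the same size for every antibody is at odds with the odds ratio of 71.1 (29.5 to 171) of S9.6 against MYBL1, which counts neighbouring peaks as independent and fell to 20 (7.52 to 53.2) without chromosome 16, where 15 of 86 S9.6 peaks or 17.4% lay at starts, and to 17.4 (5.84 to 51.6) when peaks within 20 kb were merged as well. Reads shared within local gene families stay open, since 37.4% of all S9.6 peaks lay within 50 kb of such a family (8.24% by placement), but for the 52 peaks at starts the share was 32.7%, against 20.7% by placement within the same first 1 Mb (position permutation, p = 0.058). Among autosomal S9.6 peaks elsewhere the share was 44.4% (32 of 72), above that at the starts without a difference past the threshold (Fisher's exact test, p = 0.199), and repeats near centromeres were not tested.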
